A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

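Transcript levels were measured on 9 dual-channel spotted DNA arrays of budding yeast, 3 at each of 3 sampling times (0, 1 and 4 h). Each array compared RNA of a culture given daunorubicin, labelled with Cy5 and read at 635 nm, with RNA of a parallel untreated culture, labelled with Cy3 and read at 532 nm. The dyes were never exchanged. Per the labels, the strain was a BY4741 derivative in which ERG6 was replaced by KanMX4, grown in YPD at 30 °C. They state a daunorubicin concentration of 12 mM, which was not checked here. Per the labels, a culture was divided into 3 aliquots that were diluted with fresh medium. The series text calls the replicates biological, and nothing in the sources describes separately started cultures, so the p-values may measure only the spread between these samples.

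Per the file headers, the deposited scanner files were written by GenePix Pro 5.0.1.33 from a 4000 series scanner, and they hold the raw pixel intensity of each spot and of its local background in both channels. Per the file headers, they also hold a score for each spot, namely its flag and a mark for use in scaling. The value table deposited by the authors holds a ratio per spot, the background-subtracted Cy5 median over the Cy3 median after a GenePix factor per array. Its unit was recorded as "other" in 3 columns deposited by the authors (1 h replicates 1 and 2, 4 h replicate 1), in which 1, 21 and 1 values lay at or below 0. All values in that table were equal, within 0.002, to the ratio column of the scanner file, and it covered only spots marked for scaling, 5014 to 7955 per array. The genome build and annotation behind the probes are not given in the sources used here. Probe identifiers are systematic gene names, joined to symbols through the RefSeq gene table.

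Each array held 13824 spots in 48 print blocks, with 280 blank and 384 control spots and 6388 probe identifiers, of which most had 2 spots and 12 had 34. Background was corrected by the normexp method with an offset of 50 in limma 3.58.1 under R 4.3.3, and log2(Cy5/Cy3) was normalised within each array by loess, with blank and control spots given weight 0. Spots of a probe were averaged, and 6380 probes with values on at least 2 arrays at each time were tested. Of these, 5841 matched a RefSeq locus and 6058 had values on all 9 arrays.

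A single limma model (lmFit, eBayes) with a coefficient per time was fitted to all 9 arrays. Contrasts were 1 h minus 0 h, 4 h minus 0 h, 4 h minus 1 h, and 0 h against a ratio of 1. Subtracting the 0 h arrays removes a dye effect that is constant for a probe. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 31 gene lists, with 781 genes of which 779 were measured, no gene in more than 1 list, were tested with camera at a preset correlation of 0.01 on members with values on all arrays, adjusted over the lists, and again with the correlation estimated from the data. The fry test of limma was an alternative. The model, the lists, the rule for named genes and the alternatives were fixed before the data were examined.

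The rule named the 10 largest rises and the 10 largest falls at 1 h and at 4 h, and the 5 largest per direction for 4 h minus 1 h. These had to pass the test, with all 3 arrays of a time on the same side of all 3 arrays of the other. It added up to 4 members of each list with the smallest p at 1 h or 4 h. It always named ERG6, HIS3, LEU2, MET17 and URA3, the drug pump genes PDR5, SNQ2 and YOR1, and the regulators GCR1, GCR2 and RAP1. The lists covered glycolysis and ethanol fermentation, hexose transport, gluconeogenesis and glucose-repressed carbon use, the TCA cycle, respiratory chain and ATP synthase, ergosterol synthesis, and phospholipid and fatty acid synthesis. They also covered cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerase I and III subunits, translation factors, DNA damage response, multidrug resistance, oxidative stress defence, heat shock chaperones, general stress response, proteasome, and phosphate starvation. The others were amino acid synthesis, sulphur and methionine metabolism, iron uptake and homeostasis, purine nucleotide synthesis, histones, G1 to S and G2 to M cell cycle genes, cell wall, mating and pheromone response, vacuolar ATPase, secretion and ER protein folding, alpha-cell genes, and the genes that the labels describe as deleted.

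A change was made after the data were seen. The plan was to leave out all spots with a negative flag, but flags -75 and -50 occurred at 1 h and 4 h alone, on bright spots, and flag -75 marked only spots with more treated than untreated signal. Spots marked bad (flag -100) were therefore the only ones left out, and the planned filter became an alternative. It gave 698, 1282, 308 and 679 changed genes in the 4 contrasts, in the order above, of which 686, 1240, 296 and 669 were shared with the calls reported here. With the planned filter 16, 13 and 10 lists passed at 1 h, 4 h and for 4 h minus 1 h, against 18, 14 and 13. Those that no longer passed included histones and translation factors at 1 h, hexose transport at 4 h and at 0 h, and the TCA cycle, respiratory chain and histones for 4 h minus 1 h.

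A spot counted as above background when its median exceeded the local background by 2 SDs. Where a channel of a named gene was above background on none of the 3 arrays at a time, the ratio is given as a bound or not at all. Other settings covered background correction, normalisation within and between arrays, the foreground estimate, dim spots, flags, the 0 h subtraction, the arrays in the fit, a replicate block, array weights (statmod 1.5.0), the variance prior, a 2-fold minimum, the authors' ratios, and leaving out each array in turn. Replicate numbers were checked for pairing, which the check did not settle, and the arrays were treated as unpaired. Scan day follows sampling time, so that the 2 cannot be told apart between times, while treated and untreated samples share every array. The procedure was tested on simulated data with 200 changed genes of 6380: at a true log2 change of 0.5, 1 and 1.5 it recovered 68.7%, 88.1% and 97.0% at 1 h and 70.1%, 88.1% and 98.5% at 4 h, with 4 and 6 false calls. The simulated noise was independent between genes and of the same SD on all arrays for a gene. The real arrays differed in spread, with array weights from 0.252 (1 h replicate 2) to 3.58 (0 h replicate 2). These rates therefore test the code and may not hold for the real arrays. Figures were drawn with matplotlib 3.10.9.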

Results

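RNA of a yeast strain labelled erg6Δ (ERG6 encodes a sterol methyltransferase of late ergosterol synthesis) was compared between cultures with and without the anthracycline daunorubicin, on 3 arrays at 0 h, 3 at 1 h and 3 at 4 h. The median signal over background of the treated channel was 119 to 138 intensity units at 0 h, 78 to 83 at 1 h and 107 to 124 at 4 h. That of the untreated channel was 125 to 145, 96 to 112 and 120 to 141. The treated channel lay above background on none of the 3 arrays for 744 of 6380 probes at 0 h, 2218 at 1 h and 1040 at 4 h. Falls of weakly expressed genes were therefore hardest to see at 1 h. Across genes, which are not independent replicates, log2 ratios correlated between arrays of the same time at 0.798 to 0.879 (0 h), 0.643 to 0.750 (1 h) and 0.847 to 0.884 (4 h). The number of arrays limits the precision. Unless stated otherwise, changes below are log2 ratios of treated over untreated less those at 0 h, ± SE of the fit, with 3 arrays per time. A rise or fall is one of this ratio and does not tell which culture moved, for which the channels are given further below.

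The probes of 5 genes that the labels describe as deleted, wholly or in part, were read as a test of the labels. LEU2, of leucine synthesis, was above background on 0 of 9 arrays in the treated and on 1 in the untreated channel, as was MET17, of methionine synthesis, and no ratio is given. HIS3, of histidine synthesis, whose deletion is partial, gave a clear signal in both channels on 9 arrays, from 531.5 to 752 units in the treated channel. ERG6 itself was above background on all 9 arrays in both channels, at 70 to 495.5 units (treated) and 60.5 to 350 (untreated), although the labels describe it as replaced. No probe sequences came with the arrays, so cross-hybridisation of the ERG6 and HIS3 probes could not be checked, and what the ERG6 values measure is open. Its change was 0.06 ± 0.11 at 1 h, which did not pass, and it fell at 4 h (-0.88 ± 0.11, adjusted p = 0.000717). URA3, of uracil synthesis, was above background on 7 of 9 arrays in the treated and on 5 in the untreated channel. Its probe could not be checked for cross-hybridisation either. At 1 h it was above background on none of the arrays in the untreated channel and on 1 in the treated channel. The bound there, a treated channel at least 1.22-fold higher, averages the treated values of all 3 arrays. It therefore rests mostly on values at background. Its 4 h value of 0.46 ± 0.15 did not pass (adjusted p = 0.0682). Of the 5 genes HIS3 rose at 1 h (0.48 ± 0.11) and ERG6 fell at 4 h. The rise of HIS3 did not pass without any single 0 h array or 1 h replicate 3, nor with median centring or print-tip loess. Adjusted over the list alone, 1 rose at 1 h, and 2 rose and 1 fell at 4 h. As a list they did not pass, with medians of 0.06 and 0.01 (camera adjusted p = 0.407 and 0.968). Of the 5 alpha-cell genes, silent in a MATa strain, 0 passed in the limma model at either time, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, with medians of 0.03 and 0.02 (camera adjusted p = 0.562 and 0.679).

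After 1 h with daunorubicin, against 0 h, 16 of 28 general stress genes were lower in the treated relative to the untreated cultures. HSP12, which encodes a small membrane-associated stress protein, fell by 2.08 ± 0.18 on the log2 scale, a 4.23-fold drop. The small heat shock chaperone gene HSP26 fell too (-1.70 ± 0.10). The gene of hexokinase 1, HXK1, fell (-1.75 ± 0.17), as did the glucokinase gene GLK1 (-1.62 ± 0.17). Both subunit genes of mitochondrial isocitrate dehydrogenase, IDH1 (-1.52 ± 0.08) and IDH2 (-1.46 ± 0.12), fell together. The multi-stress gene DDR2 (-1.65 ± 0.22), RTC3 (-1.79 ± 0.08), TMA10 (-1.47 ± 0.21) and YCL042W (-1.50 ± 0.22) completed the 10 largest falls that met the rule for naming, with adjusted p from 1.92e-05 to 0.00356. The largest rise was of SER3 (1.32 ± 0.14, 2.49-fold), which encodes the enzyme that starts serine synthesis from a glycolytic intermediate. Next came RPO21 (1.24 ± 0.12), the largest subunit of RNA polymerase II. NRD1 (1.01 ± 0.08), which ends short non-coding transcripts of that polymerase, rose as well. RRP5 (0.91 ± 0.10), needed for ribosomal RNA processing, and AGA1 (0.92 ± 0.16), the anchor of the mating agglutinin, rose too. So did YPS7 (1.10 ± 0.19), a cell-surface protease gene, SIT1 (0.91 ± 0.19), a siderophore transporter gene, the prolyl isomerase gene FPR1 (0.96 ± 0.24), YLR162W (1.15 ± 0.27) and YDR034C-A (0.99 ± 0.24). The adjusted p of these 10 ran from 0.000278 to 0.034.

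In all, 707 of 6380 probes changed at 1 h (11.1%), 261 higher and 446 lower, and 44 of them at least 2-fold, 5 higher and 39 lower. Median centring gave 612 higher and 641 lower, and scaling between arrays 632 and 673. The count was 362, 281 or 311 without 0 h replicate 1, 2 or 3. Without any single 0 h array, YLR162W, YDR034C-A, FPR1 and SIT1 no longer passed, nor did YDR034C-A without 1 h replicate 2 or 3 or FPR1 without any single 4 h array. YPS7 and SIT1 had 0 h ratios below 1 (-0.84 and -0.80, SD 0.41 and 0.06, n = 3) and did not pass at 1 h when the 0 h arrays were not subtracted. Nor did GPH1 (-0.14), and 6 lists did not pass either in that setting, gluconeogenesis, the respiratory chain, ribosome biogenesis, translation factors, oxidative stress and the cell wall. HTB1 and SCL1 did not pass at 1 h without 0 h replicate 3, HTB1 without 0 h replicate 1, and SCL1, HXT1 and CPR6 without 0 h replicate 2. HTB1 also did not pass with print-tip loess, scaling between arrays or the authors' ratios. HXT3 did not pass at 1 h with scaling between arrays. Without 1 h replicate 1 the lists of the respiratory chain, translation factors and oxidative stress did not pass, without 1 h replicate 3 those of translation factors, cell wall and vacuolar ATPase, and without 4 h replicate 2 that of the cell wall.

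Of the lists fixed beforehand, 18 passed at 1 h, and the general stress response alone kept its call when the correlation between genes was estimated. Of its 28 measured members 16 fell and 0 rose (20 fell adjusted over the list alone). The median was -0.45 (camera adjusted p = 4.07e-15, and adjusted p = 0.00373 with an estimated correlation). Besides HSP12 and DDR2 they included YGP1 (-1.44 ± 0.08), a secreted glycoprotein gene induced by nutrient limitation, PNC1 (-1.01 ± 0.06), the nicotinamidase, and GPH1 (-0.40 ± 0.07), glycogen phosphorylase. Of 22 heat shock chaperone genes 13 fell (14 adjusted over the list alone), among them the disaggregase gene HSP104 (-0.86 ± 0.12) and the Hsp90 co-chaperone genes STI1 (-0.77 ± 0.09) and CPR6 (-0.31 ± 0.06). The median was -0.52 (camera adjusted p = 6.6e-10, but adjusted p = 0.157 with an estimated correlation). Of 10 histone genes 5 fell (6 adjusted over the list alone), such as HTB1 (-0.92 ± 0.18) and the linker histone gene HHO1 (-0.53 ± 0.08). Their median was -0.58 (adjusted p = 0.000153, and adjusted p = 0.317 with an estimated correlation). Oxidative stress defence had 3 falls of 24 (4 adjusted over the list alone), including the peroxiredoxin gene TSA2 (-0.85 ± 0.12). Its median was -0.13 (adjusted p = 0.0139, and adjusted p = 0.299 with an estimated correlation), and -0.015 with 3 genes higher and 8 lower when the 0 h arrays were not subtracted. Proteasome subunit genes had 4 falls of 32 (4 adjusted over the list alone), including SCL1 (-0.52 ± 0.10) and RPN9 (-0.36 ± 0.06). Their median was -0.18 (adjusted p = 0.00311, and adjusted p = 0.299 with an estimated correlation).

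Genes of carbon metabolism were lower as groups at 1 h. Of 19 genes of glycolysis and fermentation 7 fell (10 adjusted over the list alone), including TPI1 (-0.67 ± 0.08), triose phosphate isomerase. The median was -0.35 (adjusted p = 6.5e-07, and adjusted p = 0.22 with an estimated correlation). The glyceraldehyde phosphate dehydrogenase genes TDH3 (-0.06 ± 0.08) and TDH2 (-0.04 ± 0.08) did not pass. Of 12 hexose transport genes 7 fell (8 fell and 1 rose adjusted over the list alone), led by the low-affinity glucose carrier genes HXT3 (-1.07 ± 0.12) and HXT1 (-0.69 ± 0.13). Their median was -0.53 (adjusted p = 0.00102, and adjusted p = 0.299 with an estimated correlation). Of 17 TCA cycle genes 6 fell (10 adjusted over the list alone), with aconitase, ACO1 (-1.41 ± 0.08), and citrate synthase, CIT1 (-0.85 ± 0.12), beside IDH1 and IDH2. Their median was -0.29 (adjusted p = 3.51e-07, and adjusted p = 0.171 with an estimated correlation). Respiratory chain and ATP synthase genes had 4 falls of 31 (5 adjusted over the list alone), such as QCR6 (-0.74 ± 0.10) of complex III. Their median was -0.14 (adjusted p = 0.00389, and adjusted p = 0.317 with an estimated correlation). Gluconeogenesis and glucose-repressed genes had 2 falls of 22 (3 adjusted over the list alone), the alcohol dehydrogenase gene ADH2 (-0.59 ± 0.08) and the cytosolic malate dehydrogenase gene MDH2 (-0.56 ± 0.06). Their median of -0.12 (adjusted p = 0.00389, and adjusted p = 0.157 with an estimated correlation) turned to 0.078 with median centring.

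Genes of sterols and of drug efflux were lower too. Of 23 ergosterol synthesis genes 9 fell at 1 h (11 adjusted over the list alone), among them ERG11 (-0.67 ± 0.08), the target of azole drugs, and ERG3 (-0.85 ± 0.12), the C-5 desaturase. Their median was -0.28 (adjusted p = 5.88e-05, and adjusted p = 0.22 with an estimated correlation). Of 21 multidrug resistance genes 5 fell (6 adjusted over the list alone), with a median of -0.16 (adjusted p = 0.000365, and adjusted p = 0.157 with an estimated correlation). The ABC transporter genes PDR5 (-1.28 ± 0.16) and SNQ2 (-1.00 ± 0.10) and the reductase gene GRE2 (-0.83 ± 0.08) fell, while YOR1, a further ABC transporter gene, did not pass (-0.19 ± 0.12, adjusted p = 0.337). Of 24 cell wall genes 6 fell and 1 rose (8 and 4 adjusted over the list alone), including PST1 (-0.78 ± 0.12) and PIR1 (-0.63 ± 0.09), both for wall glycoproteins. Their median was -0.15 (adjusted p = 0.023, and adjusted p = 0.299 with an estimated correlation).

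The groups that were higher at 1 h belong to the making of ribosomes, to translation and to the vacuolar proton pump, and 0 of these lists kept the call with an estimated correlation. Of 139 cytosolic ribosomal protein genes 17 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 0.44 (adjusted p = 2.82e-15, and adjusted p = 0.367 with an estimated correlation). RPS11B (0.68 ± 0.09) is an example, and RPL6A (0.53 ± 0.09) and RPL7B (0.59 ± 0.11) passed as well, though not with median centring. Of 50 ribosome biogenesis genes 17 rose and 1 fell (25 and 1 adjusted over the list alone), with a median of 0.28 (adjusted p = 1.61e-09, and adjusted p = 0.171 with an estimated correlation). When the 0 h arrays were not subtracted the ribosome biogenesis median was 0.032, with 16 genes higher and 7 lower, and the list did not pass. RRP9 (0.51 ± 0.07), of the U3 particle that cuts ribosomal RNA precursors, rose, and the RNA helicase gene DBP2 fell (-0.98 ± 0.12). Of 20 RNA polymerase I and III subunit genes 8 rose (13 adjusted over the list alone), with a median of 0.26 (adjusted p = 7.46e-07, and adjusted p = 0.13 with an estimated correlation). RPA190, the largest subunit of RNA polymerase I, rose by 0.51 ± 0.09 from a 0 h ratio of -0.51 (SD 0.08, n = 3), and its value without the 0 h arrays was -0.0033. Translation factor genes had 2 rises of 22 (5 adjusted over the list alone), among them TIF3 (0.46 ± 0.07), an initiation factor gene that did not pass with median centring. The median was 0.10 (adjusted p = 0.0329, and adjusted p = 0.22 with an estimated correlation). Of 14 vacuolar ATPase genes 3 rose (3 adjusted over the list alone), VMA1, VMA2 and VMA4 (0.56 ± 0.13, 0.68 ± 0.15 and 0.54 ± 0.08). The median was 0.19 (adjusted p = 0.0114, and adjusted p = 0.299 with an estimated correlation).

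The remaining lists did not pass at 1 h. Of 20 DNA damage response genes 3 fell and 0 rose (3 and 0 adjusted over the list alone), including RNR1 (-0.70 ± 0.08), the large subunit of ribonucleotide reductase, with a median of -0.03 (adjusted p = 0.474). Amino acid synthesis had 3 rises and 10 falls of 44 (6 and 12 adjusted over the list alone, median -0.08, adjusted p = 0.0991), with ILV5 (-1.03 ± 0.09) of branched-chain synthesis among the falls. Purine synthesis had 1 rise and 5 falls of 17 (1 and 5 adjusted over the list alone, median -0.08, adjusted p = 0.0546), and phospholipid and fatty acid synthesis 2 falls of 17 (2 adjusted over the list alone, median -0.09, adjusted p = 0.29). Mating genes had 2 rises, AGA1 and PRM1 (0.73 ± 0.09), and 1 fall of 21 (2 and 1 adjusted over the list alone, median 0.13, adjusted p = 0.0546). Sulphur and methionine genes had 2 rises and 1 fall of 25 (3 and 3 adjusted over the list alone, median -0.01, adjusted p = 0.981), with CYS3 (0.56 ± 0.07) of cysteine synthesis among the rises, though not with median centring. Iron genes had 2 rises and 1 fall of 23 (2 and 2 adjusted over the list alone, median -0.05, adjusted p = 0.562). Their rises were SIT1 and the siderophore-binding wall protein gene FIT3 (0.83 ± 0.15), and their fall was ISU1 (-1.00 ± 0.07), the scaffold of iron-sulphur cluster assembly. Phosphate starvation genes had 2 falls of 18 (2 rises and 2 falls adjusted over the list alone, adjusted p = 0.981), and secretion and ER folding genes 3 falls of 18 (1 and 3 adjusted over the list alone, adjusted p = 0.562). G1 to S genes had 1 fall of 20 and G2 to M genes 1 rise of 16 (0 and 0 adjusted over the list alone, adjusted p = 0.981 for both). The median was 0.01 for phosphate and 0.0064 for secretion genes, whose mean and test pointed down, and -0.0018 for G2 to M genes, whose test pointed up.

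**Figure D1:**
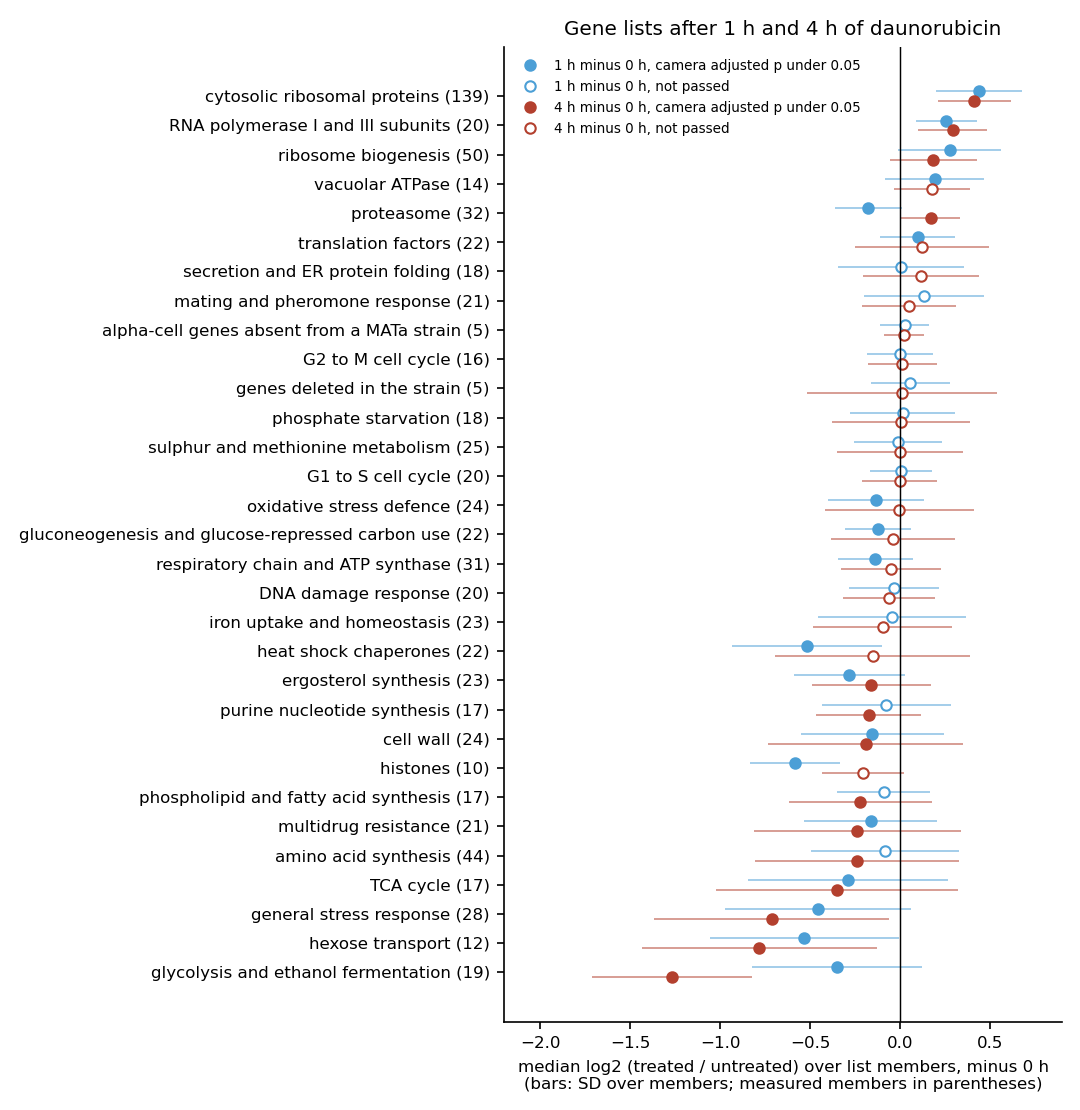
Median log2 ratio of treated over untreated cultures, less that at 0 h, for the 31 gene lists (vertical axis) at 1 h and 4 h, with bars for the SD over members and filled points where camera at the preset correlation passed. General stress genes stood at -0.45 and -0.71, glycolysis at -0.35 and -1.27, and ribosomal protein genes at 0.44 and 0.41.

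After 4 h with daunorubicin, the ratios of glycolytic genes had fallen almost throughout the pathway, and those of stress genes lay further below 0 h. SER3 rose most of the genes that met the rule for naming. SER3 rose by 2.70 ± 0.14, or 6.48-fold (adjusted p = 9.29e-06). CHA1, which encodes the serine and threonine deaminase that breaks serine down, fell by 2.65 ± 0.08 on the log2 scale (adjusted p = 6.96e-07), and HSP12 fell further (-2.92 ± 0.18, a 7.59-fold drop). The other large falls were of HXK1 (-2.31 ± 0.17), HSP26 (-2.17 ± 0.10), ACO1 (-2.04 ± 0.08), DDR2 (-1.99 ± 0.22), TMA10 (-1.95 ± 0.21), YGP1 (-1.89 ± 0.08), IDH2 (-1.82 ± 0.12) and PRB1 (-1.85 ± 0.09), the vacuolar proteinase B gene, with adjusted p up to 0.000525. TIP1 (1.18 ± 0.09), a cell wall mannoprotein gene, OLI1 (1.50 ± 0.29), a subunit of ATP synthase encoded in the mitochondrial genome, RPO21 (1.01 ± 0.12) and AGA1 (0.93 ± 0.16) rose. So did the glutaredoxin gene GRX8 (0.92 ± 0.13), the ubiquitin-activating enzyme gene UBA1 (0.92 ± 0.14), SIT1 (1.03 ± 0.19), YDR034C-A (1.38 ± 0.24) and YLR162W (1.12 ± 0.27), with adjusted p up to 0.0206. UBA1 and SIT1 began from 0 h ratios below 1 (-0.59 and -0.80, SD 0.13 and 0.06, n = 3), and at 4 h their ratios were 0.33 (SD 0.26) and 0.23 (SD 0.31).

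In all, 1263 of 6380 probes changed at 4 h (19.8%), 546 higher and 717 lower, and 106 of them at least 2-fold, 13 higher and 93 lower. The authors' ratios gave 432 higher and 378 lower of fewer tested genes, and the count was 719, 634 or 658 without 0 h replicate 1, 2 or 3 and 807 without 4 h replicate 2. YLR162W did not pass without any single 0 h array, and SIT1 did not pass when the 0 h arrays were not subtracted. Nor did RAD51 (-0.15, from a 0 h ratio of 0.26), and HAC1 did not pass without 0 h replicate 2.

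Of 19 genes of glycolysis and fermentation, 18 fell and 0 rose at 4 h (19 fell adjusted over the list alone), with a median of -1.27 (adjusted p = 6.68e-18, but adjusted p = 0.0688 with an estimated correlation). The glyceraldehyde phosphate dehydrogenase genes TDH1 (-1.55 ± 0.10), TDH2 (-1.32 ± 0.08) and TDH3 (-1.36 ± 0.08), which are closely similar in sequence, and TPI1 (-1.24 ± 0.08) were among them. GCR1, an activator of glycolytic genes, fell by 0.61 ± 0.11 on the log2 scale (adjusted p = 0.00636), while its partners GCR2 (0.04 ± 0.06) and RAP1 (0.02 ± 0.07) did not pass. At 1 h the treated signal of GCR1 lay at background and the untreated channel was at least 1.35-fold higher. Of 12 hexose transport genes 8 fell and 1 rose (8 and 1 adjusted over the list alone), with HXT1 at -1.36 ± 0.13 and HXT3 at -1.10 ± 0.12. Their median was -0.78 (adjusted p = 0.003, and adjusted p = 0.413 with an estimated correlation). Of 17 TCA cycle genes 9 fell (10 adjusted over the list alone), with a median of -0.35 (adjusted p = 2.7e-07, and adjusted p = 0.156 with an estimated correlation). IDH1 (-1.67 ± 0.08) and CIT1 (-1.15 ± 0.12) were among them. The gluconeogenesis list had 4 falls of 22 (4 adjusted over the list alone), ADH2 (-1.38 ± 0.08) and MDH2 (-0.72 ± 0.06) among them, and its median of -0.04 did not pass (adjusted p = 0.0711). Respiratory chain genes had 1 rise and 4 falls of 31 (1 and 4 adjusted over the list alone, median -0.05, adjusted p = 0.416).

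Of 28 general stress genes, 24 fell and 0 rose at 4 h (25 fell adjusted over the list alone), with a median of -0.71 (adjusted p = 6.33e-19, and adjusted p = 0.00185 with an estimated correlation). GPH1 (-1.27 ± 0.07) joined HSP12, DDR2 and YGP1 there. Heat shock chaperone genes had 2 rises and 6 falls of 22 (2 and 6 adjusted over the list alone, median -0.15), and the list no longer passed (adjusted p = 0.0763). CPR6 rose at 4 h (0.40 ± 0.06) while HSP104 fell (-0.78 ± 0.12). Of 32 proteasome genes 6 rose (6 adjusted over the list alone), such as PRE10 (0.43 ± 0.06) and PRE5 (0.33 ± 0.06) of the core particle. Their median was 0.17 (adjusted p = 0.0125, and adjusted p = 0.439 with an estimated correlation). When the 0 h arrays were not subtracted the proteasome median was 0.07, with 10 genes higher and 8 lower, and the list did not pass. Oxidative stress genes had 2 rises and 4 falls of 24 (2 and 5 adjusted over the list alone, median -0.0050, adjusted p = 0.469), among which TSA2 fell (-1.48 ± 0.12) and CCS1 (0.36 ± 0.07), the copper chaperone of superoxide dismutase, rose. DNA damage response genes had 5 falls of 20 (5 adjusted over the list alone, median -0.06, adjusted p = 0.061), including RNR1 (-0.90 ± 0.08), RNR4 (-0.41 ± 0.07) and the recombinase gene RAD51 (-0.41 ± 0.08). Histone genes had 1 fall of 10, HHO1 (-0.53 ± 0.08), and 1 adjusted over the list alone (median -0.21, adjusted p = 0.137).

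Genes of membranes, walls and drug efflux were lower at 4 h as well. Of 21 multidrug resistance genes 9 fell (10 adjusted over the list alone), with a median of -0.24 (adjusted p = 3.41e-05, and adjusted p = 0.0688 with an estimated correlation). PDR5 fell by 1.59 ± 0.16 on the log2 scale, SNQ2 (-1.08 ± 0.10) and the polyamine transporter gene TPO3 (-1.35 ± 0.14) fell too, and YOR1 did not pass (-0.32 ± 0.12, adjusted p = 0.107). Of 17 phospholipid and fatty acid synthesis genes 8 fell (8 adjusted over the list alone), with a median of -0.22 (adjusted p = 0.000671, and adjusted p = 0.0688 with an estimated correlation). They included INO1 (-1.18 ± 0.08), inositol phosphate synthase, ITR1 (-0.80 ± 0.09), an inositol transporter, OLE1 (-0.88 ± 0.11), the fatty acid desaturase, and FAS1 (-0.62 ± 0.09), a fatty acid synthase subunit. Of 23 ergosterol synthesis genes 7 fell (8 adjusted over the list alone), such as ERG11 (-0.84 ± 0.08) and ERG5 (-0.78 ± 0.11). Their median was -0.16 (adjusted p = 0.00102, and adjusted p = 0.352 with an estimated correlation). Of 24 cell wall genes 11 fell and 1 rose (11 and 2 adjusted over the list alone), with a median of -0.19 (adjusted p = 0.000267, and adjusted p = 0.156 with an estimated correlation). PST1 (-1.33 ± 0.12) and the chitin synthase gene CHS1 (-1.14 ± 0.14) fell, and TIP1 was the rise.

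Of 44 amino acid synthesis genes, 17 fell and 2 rose at 4 h (19 and 2 adjusted over the list alone), with a median of -0.24 (adjusted p = 0.000106, and adjusted p = 0.448 with an estimated correlation). ARG1 (-1.18 ± 0.07) of arginine synthesis, ILV5 (-1.07 ± 0.09) and ARO3 (-0.97 ± 0.10) of aromatic amino acid synthesis fell, and SER3 was a rise. Of 17 purine synthesis genes 6 fell and 1 rose (6 and 1 adjusted over the list alone), with ADE17 (-0.83 ± 0.16) among the falls. Their median was -0.17 (adjusted p = 0.0287, and adjusted p = 0.536 with an estimated correlation). Ribosomal protein genes had 14 rises and 0 falls of 139, and 1 rise adjusted over the list alone, with a median of 0.41 (adjusted p = 1.11e-09, and adjusted p = 0.582 with an estimated correlation). Ribosome biogenesis genes had 12 rises and 1 fall of 50 (13 and 1 adjusted over the list alone) and a median of 0.19 (adjusted p = 0.000248, and adjusted p = 0.384 with an estimated correlation), which was -0.041 when the 0 h arrays were not subtracted. Of 20 RNA polymerase I and III genes 12 rose (15 adjusted over the list alone), such as RPA12 (0.63 ± 0.13), with a median of 0.29 (adjusted p = 2.3e-06, and adjusted p = 0.0688 with an estimated correlation). Translation factor genes had 6 rises and 5 falls of 22 (7 and 5 adjusted over the list alone, median 0.12, adjusted p = 0.529). Their falls included TEF1 (-0.61 ± 0.09) and TEF2 (-0.55 ± 0.08), which encode the same elongation factor protein, and TEF1 turned to 0.54 with print-tip loess.

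The other lists did not pass at 4 h. Mating genes had 3 rises of 21 (3 adjusted over the list alone, median 0.05, adjusted p = 0.233), and vacuolar ATPase genes 1 rise of 14, VMA4 (0.48 ± 0.08), and 1 adjusted over the list alone (median 0.18, adjusted p = 0.105). Sulphur and methionine genes had 7 rises and 6 falls of 25 (7 and 6 adjusted over the list alone, adjusted p = 0.696), with CYS3 (0.77 ± 0.07) and MET16 (0.40 ± 0.06) among the rises and the methionine synthase gene MET6 (-0.58 ± 0.10) among the falls. Phosphate starvation genes had 5 rises and 5 falls of 18 (5 and 6 adjusted over the list alone, adjusted p = 0.785). Iron genes had 3 rises and 3 falls of 23 (3 and 4 adjusted over the list alone, median -0.10, adjusted p = 0.416), and ISU1 (-1.01 ± 0.07) was again lower. Secretion and ER folding genes had 1 rise, SCJ1 (0.40 ± 0.06), and 1 fall, HAC1 (-0.97 ± 0.21), of 18 (1 and 1 adjusted over the list alone, median 0.11, adjusted p = 0.137). G1 to S genes had 1 fall of 20, CLN2 (-0.38 ± 0.11), and 0 adjusted over the list alone (adjusted p = 0.858), and G2 to M genes had 1 rise and 2 falls of 16 (1 and 2 adjusted over the list alone, median 0.01, adjusted p = 0.881). Median, mean and test differed in sign for sulphur (median -0.00034), phosphate (median 0.0049) and G1 to S genes (median -0.0028), and for the deleted genes.

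The direct comparison of 4 h with 1 h asked which ratios moved between the sampling times. Of the glycolytic genes 13 of 19 were lower at 4 h than at 1 h, while 10 of 32 proteasome genes and 4 of 22 heat shock chaperone genes were higher and 1 chaperone gene was lower. These 3 lists passed at the preset correlation only (adjusted p = 0.0841, 0.0841 and 0.266 with an estimated correlation). TDH1 (-1.36 ± 0.10), TDH3 (-1.30 ± 0.08) and TDH2 (-1.28 ± 0.08) differed by more than 2-fold, as did INO1 (-1.34 ± 0.08), CHA1 (-1.39 ± 0.08) and JIP3 (-1.45 ± 0.09), an open reading frame of doubtful coding status. SER3 (1.38 ± 0.14), TIP1 (0.88 ± 0.09) and the metallothionein genes CUP1-1 (0.91 ± 0.17) and CUP1-2 (0.93 ± 0.19), identical copies that probes cannot tell apart, were higher at 4 h. VAR1, a mitochondrially encoded ribosomal protein gene, also ranked there, but its treated signal at 1 h lay at background, with the untreated channel at least 1.51-fold higher. From 0 h, with 2 arrays, to 4 h, with 3, it rose by 2.62 ± 0.32 (adjusted p = 0.00114), from a ratio of -1.25 (SD 0.08, n = 2) to one of 1.38.

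Between 1 h and 4 h, 308 of 6380 probes differed (4.83%), 127 higher and 181 lower at 4 h, and 14 of them at least 2-fold, 2 higher and 12 lower. The estimate of the spread was shared with the 0 h arrays, whose array weights were higher (2.04 to 3.58, against 0.252 to 0.969 at 1 h and 4 h). With the 1 h and 4 h arrays alone 75 probes differed, 18 higher and 57 lower. Median centring gave 277 higher and 100 lower and the authors' ratios 122 and 104. The count was 163, 146 or 146 without 0 h replicate 1, 2 or 3, 199 or 590 without 1 h replicate 1 or 2, and 145, 152 or 196 without 4 h replicate 1, 2 or 3. CUP1-1 and CUP1-2 did not pass without 1 h replicate 1 or any single 4 h array, nor CUP1-2 without any single 0 h array. HSP26 did not pass without any single 0 h or 4 h array or 1 h replicate 1. Without 1 h replicate 1 the lists of the TCA cycle, respiratory chain, ribosome biogenesis, multidrug resistance, amino acid synthesis, histones and cell wall did not pass. Nor did the TCA cycle, respiratory chain, ribosome biogenesis, amino acid synthesis and histones without 1 h replicate 3, or the TCA cycle, respiratory chain, multidrug resistance and amino acid synthesis without 4 h replicate 2. The respiratory chain and ribosome biogenesis did not pass without 4 h replicate 1, nor did ribosome biogenesis without 4 h replicate 3. With the planned filter on all negative flags the TCA cycle, respiratory chain and histones did not pass, nor did histones and translation factors at 1 h or hexose transport at 4 h.

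By list, 13 of 31 differed between the times, and the general stress response alone kept its call with an estimated correlation. It was lower at 4 h (median -0.23, 8 of 28 lower and 1 higher, 13 and 2 adjusted over the list alone, adjusted p = 5.2e-07, and adjusted p = 0.0345 with an estimated correlation), with GPH1 at -0.86 ± 0.07 and PNC1 at 0.45 ± 0.06. Glycolysis had 13 of 19 genes lower (14 adjusted over the list alone, median -0.80, adjusted p = 2.77e-15, and adjusted p = 0.0841 with an estimated correlation). Proteasome genes were higher, 10 of 32 (17 adjusted over the list alone, median 0.27, adjusted p = 3.35e-11, and adjusted p = 0.0841 with an estimated correlation), including SCL1 (0.62 ± 0.10). Heat shock chaperones had 4 of 22 higher and 1 lower (9 and 1 adjusted over the list alone, median 0.30, adjusted p = 6.54e-07, and adjusted p = 0.266 with an estimated correlation), with CPR6 (0.72 ± 0.06) and STI1 (0.63 ± 0.09) higher and HSP26 (-0.46 ± 0.10) lower. Phospholipid synthesis had 5 of 17 lower (7 lower and 2 higher adjusted over the list alone, median -0.10, adjusted p = 0.0024, and adjusted p = 0.0841 with an estimated correlation). Secretion and ER folding had 1 of 18 higher, FPR2 (0.61 ± 0.08), and 1 adjusted over the list alone (median 0.15, adjusted p = 0.00537, and adjusted p = 0.0841 with an estimated correlation). Amino acid synthesis had 5 of 44 lower and 1 higher (7 and 2 adjusted over the list alone, median -0.11, adjusted p = 0.00364, and adjusted p = 0.602 with an estimated correlation), with ARG1 at -0.80 ± 0.07. Multidrug resistance had 3 of 21 lower and 1 higher (5 and 1 adjusted over the list alone, median -0.10, adjusted p = 0.0211, and adjusted p = 0.334 with an estimated correlation), with TPO3 at -1.00 ± 0.14. Cell wall genes had 3 of 24 lower and 1 higher (9 and 2 adjusted over the list alone, median -0.25, adjusted p = 0.0162, and adjusted p = 0.365 with an estimated correlation). TCA cycle genes had 2 of 17 lower (2 adjusted over the list alone, median -0.12, adjusted p = 0.0262, and adjusted p = 0.602 with an estimated correlation), including ACO1 (-0.62 ± 0.08). In ribosome biogenesis (median -0.077, adjusted p = 0.0211), the respiratory chain (median 0.15, adjusted p = 0.0437) and the histones (median 0.31, adjusted p = 0.0072), 0 members passed, 0 adjusted over the list alone, and each had adjusted p = 0.602 with an estimated correlation. With median centring the medians of the TCA cycle, ribosome biogenesis and amino acid synthesis turned to 0.024, 0.047 and 0.10, and with the authors' ratios TPO3 turned to 0.65. Median, mean and test differed in sign for gluconeogenesis (0.05), ergosterol (-0.0089), iron (0.03), mating (0.0096) and G1 to S genes (0.0046), none of which passed.

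The calls at 1 h and 4 h were shared to a large extent. Both times saw 153 probes higher and 318 lower, among them SER3, RPO21, HSP12, IDH1 and PDR5. The 3 that changed in opposite directions, of which 2 were singled out after their values were seen, were CPR6, PAD1 (-0.29 ± 0.06 at 1 h, 0.19 ± 0.06 at 4 h), of flavin-linked decarboxylation, and NUP85 (0.37 ± 0.08 and -0.29 ± 0.08), of the nuclear pore. Independent calls would give 22.3 and 50.1. Across genes the changes at 1 h and 4 h correlated at 0.760. Both contrasts subtract the same 0 h arrays, which cannot be divided into groups of 2 or more, so part of the excess may come from them. Simulated unchanged groups set against the same 0 h arrays shared 0 calls on average over 20 draws and correlated at 0.182. With no gene changed hardly any call is made at either time, so the 0 does not tell how much the shared arrays add to the real overlap. The covariance of the changes over genes was 0.0676, against 0.00236 for the simulated groups. This argues against the spread between the 0 h arrays as the main source of the correlation. Groups unchanged from 0 h hold no offset of the 0 h arrays that is absent later, so such an offset is not covered. Against a ratio of 1, without the 0 h arrays, 802 probes were higher and 950 lower at both times with 44 opposite. A dye effect constant for a probe is left in at both times there and can itself make the calls agree. Over 5298 probes outside the lists, the slopes of the 1 h and 4 h on the 0 h ratios, relative to that between 0 h arrays, were 0.864 and 0.812. These larger counts therefore cannot decide on a shared response. The shared count was 252, 203 or 221 without 0 h replicate 1, 2 or 3.

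**Figure D2:**
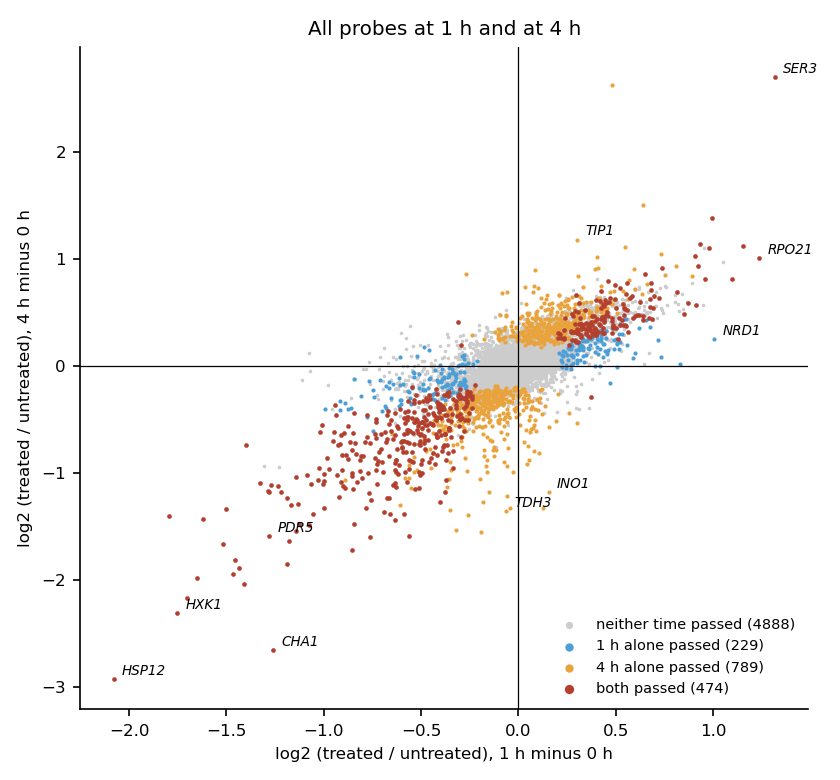
Change in log2 ratio from 0 h at 4 h (vertical axis) against that at 1 h (horizontal axis) for 6380 probes, coloured by the times at which a probe passed. SER3 lies at 1.32 and 2.70, HSP12 at -2.08 and -2.92, and TDH3 at -0.06 and -1.36.

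At 0 h, when the drug had only just been added, ratios that differ from 1 may hold dye effects and differences between the cultures, which were not tested. Of 6380 probes 722 differed from 1, 246 higher and 476 lower, and the 36 with at least a 2-fold ratio were lower in the treated channel. The desaturase gene OLE1 (-0.67, SD 0.08, n = 3), HXT3 (-0.69, SD 0.19, n = 3) and YPS7 (-0.84, SD 0.41, n = 3) were among those below 1. Of the 31 lists 11 passed, 4 above and 7 below 1, and 0 kept the call with an estimated correlation. Ribosome biogenesis genes were lower, 21 of 50 (31 lower and 1 higher adjusted over the list alone, median -0.23, adjusted p = 1.35e-10, and adjusted p = 0.219 with an estimated correlation), and 8 of 28 general stress genes were higher (12 higher and 2 lower adjusted over the list alone, median 0.13, adjusted p = 0.000613, and adjusted p = 0.141 with an estimated correlation). The other lists were hexose transport (-0.16), amino acid synthesis (-0.15), phosphate (-0.13), proteasome (-0.09), RNA polymerase I and III (-0.09) and purine synthesis (-0.09) below 1. Above 1 were gluconeogenesis (0.10), the respiratory chain (0.12) and oxidative stress (0.09). These 9 had adjusted p from 0.00204 to 0.0272, and adjusted p from 0.172 to 0.579 with an estimated correlation. The gluconeogenesis median turned to -0.11 with the authors' ratios. The split was 84 higher and 300 lower with median centring, 1114 and 1399 with scaling between arrays, and 174 and 189 with the authors' ratios, and the count fell to 100, 4 or 50 without 0 h replicate 1, 2 or 3 and was 1150 without 1 h replicate 2.

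The channels of each array were also read singly. Their values were rebuilt from the loess-normalised ratio and a brightness given the same distribution on all arrays, so they are not independent readings. From 0 h to 4 h the median of the glycolysis list changed by -1.01 (SE 0.067) in the treated and by -0.00076 (SE 0.075) in the untreated channel. For general stress genes the treated channel changed by -0.16 (SE 0.034) and the untreated channel by 0.64 (SE 0.025). At 1 h the latter stood at 0.09 (SE 0.069) and 0.64 (SE 0.032). Ribosomal protein genes changed by 0.29 (SE 0.066) in the treated and -0.08 (SE 0.059) in the untreated channel at 4 h. Levels between arrays also differ by scan day, which follows time.

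**Figure D3:**
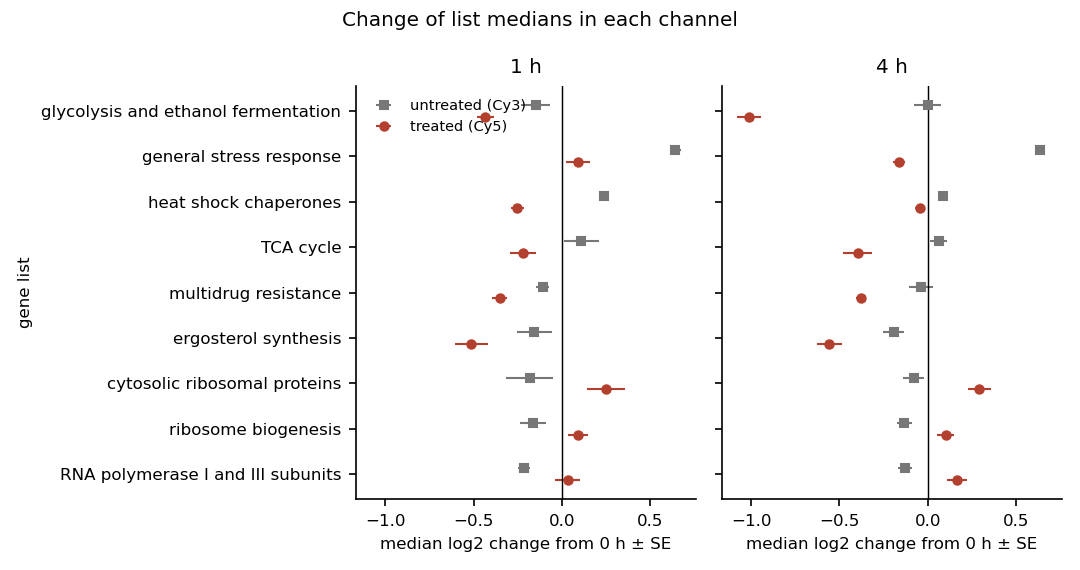
Change from 0 h of the median log2 signal of 9 gene lists in the treated and in the untreated channel at 1 h and 4 h, with bars for the SE over arrays. The signals were rebuilt from the normalised ratio and brightness. General stress genes stood at 0.64 in the untreated channel at both times, and glycolysis genes at -1.01 in the treated channel at 4 h.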

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

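The brightness test of the glycolytic genes was chosen after its result was seen, and the other tests in this part were set before theirs. Glycolytic genes differed between the sampling times by the test of the difference itself, with TDH1 at -1.36, TDH3 at -1.30, TDH2 at -1.28 and TPI1 at -0.57 for 4 h minus 1 h, and a list median of -0.80 (adjusted p = 0.0841 with an estimated correlation). Their 4 h median of -1.27 (SD over members 0.45) was set against 124 probes outside the list of like brightness, whose median was 0.31. Genes of other lists were not left out of these. Ribosomal protein genes are of like brightness (median untreated percentile 97.2, against 99.3) and stood at 0.41. Loess also ties bright spots to each other, so this cannot decide on a bias shared by bright spots. A rise in the untreated cultures is argued against by the untreated channel of the glycolytic genes, which changed by -0.00076 (SE 0.075) from 0 h to 4 h. Scan day follows sampling time and cannot be told apart from it between arrays, so the share of each channel rests on levels that a scan could shift. It also rests on a brightness made alike over the arrays. A response of glycolytic genes to daunorubicin between 1 h and 4 h stays open as a hypothesis.

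General stress genes also differed between the times, with a median of -0.23 for 4 h minus 1 h and HSP12 at -0.85, YGP1 at -0.45, GPH1 at -0.86 and PNC1 at 0.45, although HSP12 no longer passed in 12 of the alternatives, among them leaving out any single 0 h array, and YGP1 in 7. For their 4 h median of -0.71 (SD over members 0.65), 272 probes of like brightness gave -0.0043. Loess sets the typical ratio at each brightness near 0, so this value was to be foreseen and cannot decide on a brightness bias. Their untreated channel rose by 0.64 (SE 0.025) from 0 h to 4 h while the treated channel changed by -0.16 (SE 0.034), in line with a rise in the untreated cultures as a cause of the lower ratio against 0 h. It does not account for the difference between 1 h and 4 h, since the untreated channel already stood at 0.64 (SE 0.032) at 1 h and the treated channel went from 0.09 (SE 0.069) to -0.16, on levels that a scan could shift. An effect of the drug on these genes stays open, and the files hold no growth measure that could test a difference in growth between the cultures.

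Ribosome biogenesis genes stood higher at 1 h than at 0 h (median 0.28, SD over members 0.29), with adjusted p = 0.171 with an estimated correlation, and their 0 h ratio was below 1 (median -0.23). When the 0 h arrays were not subtracted the median was 0.032 and the list did not pass. The slope of the 1 h on the 0 h ratios over 49 members, relative to that between 0 h arrays, was 1.41 (SE 0.34), but a shift alike in all members leaves this slope as it is, so an offset of the 0 h arrays that is absent at 1 h stays open. The 485 probes of like brightness had a median of -0.0069 (SD over probes 0.30). It lies below the list by less than the spread over members, the bound set beforehand, or over probes. That spread is one of single genes and not the error of a median. Loess also sets the typical ratio at each brightness near 0, so this value was to be foreseen. The test therefore cannot decide on a bias of probes of that brightness. A response to the drug stays open beside these.

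Other genes for which the change from 0 h differed between 1 h and 4 h, by the same test, are given as log2 ratios at 4 h minus 1 h. Higher at 4 h were SER3 (1.38), CUP1-2 (0.93), CUP1-1 (0.91), TIP1 (0.88), CPR6 (0.72), STI1 (0.63), SCL1 (0.62), FPR2 (0.61), PRE5 (0.42), PRE10 (0.39) and RTC3 (0.39). Lower by more than 2-fold were JIP3 (-1.45), CHA1 (-1.39) and INO1 (-1.34). TPO3 (-1.00), ERG6 (-0.94, from a probe that could not be checked for cross-hybridisation), FIT3 (-0.81), ARG1 (-0.80), ADH2 (-0.80), NRD1 (-0.76), TEF1 (-0.70), HXT1 (-0.67), PRB1 (-0.66), PRM1 (-0.65), TSA2 (-0.63) and ACO1 (-0.62) were lower. So were TEF2 (-0.56), PST1 (-0.54), HSP26 (-0.46), ITR1 (-0.46), PIR1 (-0.37) and TIF3 (-0.33). Of the lists, proteasome (0.27), heat shock chaperones (0.30), histones (0.31), secretion and ER folding (0.15) and the respiratory chain (0.15) had higher medians at 4 h. Cell wall (-0.25), TCA cycle (-0.12), amino acid synthesis (-0.11), multidrug resistance (-0.10), phospholipid synthesis (-0.10) and ribosome biogenesis (-0.077) had lower ones. With an estimated correlation 0 of these 11 lists kept the call (adjusted p = 0.0841 to adjusted p = 0.602 with an estimated correlation), and in the histones, the respiratory chain and ribosome biogenesis 0 members passed. CUP1-1, CUP1-2, RTC3, HSP26, PST1, PIR1, TIF3, ITR1 and TSA2 did not pass without any single 4 h array, nor FIT3 and HXT1 without 4 h replicate 1 or 2. Without any single 0 h array CUP1-2, RTC3, HSP26, PST1, PIR1, TIF3 and HXT1 did not pass. Of all alternatives PIR1 lost the call in 18, PST1 in 15, RTC3 and HSP26 in 14, TIF3 in 13, and ITR1 and TSA2 in 11.

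The spot flags -75 and -50 were not used in the comparisons, while the spots that they marked were kept. Flag -75 marked 601 spots, 264 at 1 h and 337 at 4 h, and 0 at 0 h, all with more treated than untreated signal. Of the probe identifiers it marked, 76 of 85 at 1 h and 79 of 111 at 4 h were cytosolic ribosomal protein genes. Of these 85 and 111 identifiers, 8 and 4 passed against 0 h, as rises. Flag -50 marked 591 spots, 297 at 1 h and 294 at 4 h, of which 509 had less treated than untreated raw signal, as had 59629 of the spots without a flag, against 44525 with more. After normalisation the probe identifiers with flag -50 split into 46 higher and 35 lower at 1 h and 22 and 30 at 4 h, and those of them that passed against 0 h were falls (23 at 1 h and 20 at 4 h), with 8 and 12 glycolysis genes among the marked identifiers. The brighter channel of these spots had a median of 17832 and 21543 intensity units, against 129 for spots without a flag. The meaning of these flags is not given in the files.

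Other splits of 6 arrays into 3 and 3 gave at most 11 changed genes for 1 h against 0 h (real split 707), 0 for 4 h against 0 h (1263) and 1 for 4 h against 1 h (308). They gave at most 13, 13 and 11 passing lists, against 18, 14 and 13. For each of these results 1 of 10 splits, the real one, reached the real value, and 10 splits are too few for a share under 0.05.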

How the results depend on the processing

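The filter on all negative flags was the planned setting and the reported one was chosen after the data were seen; the other alternatives were planned. Of 5406 values of named genes under alternatives (230 results), 4887 kept their direction and side of the threshold, 514 kept their direction and no longer passed, and 5 reversed. Of 1488 list medians (56 results) the counts were 1254, 228 and 6. In the values below, counts of changed genes refer to 1 h (707), 4 h (1263), 4 h minus 1 h (308) and 0 h (722), lists to the same contrasts (18, 14, 13 and 11) and shared calls to 1 h with 4 h (471). Without background subtraction 8 lists passed for 4 h minus 1 h. Plain subtraction, with 5542 genes tested, gave 690 at 4 h, 120 and, at 0 h, 250. Print-tip loess turned TEF1 from -0.61 to 0.54 at 4 h and from -0.70 to 0.43 for 4 h minus 1 h. Median centring gave 1253 at 1 h and 384 at 0 h, and turned gluconeogenesis at 1 h to 0.078 and the TCA cycle, ribosome biogenesis and amino acid synthesis for 4 h minus 1 h to 0.024, 0.047 and 0.10. Scaling between arrays gave 1305 at 1 h, 132 for 4 h minus 1 h, 2513 at 0 h and 843 shared. Without 0 h subtraction 2558 changed at 1 h and 3010 at 4 h, 1752 were shared, and RPA190 at 1 h (-0.0033), YPS7 at 4 h (-0.033) and ribosome biogenesis at 4 h (-0.041) reversed; 4 h minus 1 h does not depend on that subtraction by construction. Fitting the compared times alone gave 2065 at 4 h, 75 and, at 0 h, 2615, and array weights 2068, 195 and 3136, with the lowest weight for 1 h replicate 2 (0.252). Requiring 2-fold left 44, 106, 14 and 36 genes, 38 shared and 0, 1, 0 and 0 lists by construction. An estimated correlation left 1, 1, 1 and 0 lists. The authors' ratios, with 2747 genes tested, gave 810 at 4 h and 363 at 0 h, with 11 lists at 1 h, 8 for 4 h minus 1 h and 5 at 0 h, TPO3 for 4 h minus 1 h at 0.65 and gluconeogenesis at 0 h at -0.11. Simulated unchanged groups shared 0 calls, as hardly any are made where no gene changes. Apart from the fewer genes tested and the 2-fold rule, the cause was not tested. Leaving out an array gave 281 (0 h replicate 2) to 864 (1 h replicate 1) genes at 1 h, with 362 and 311 without 0 h replicates 1 and 3. At 4 h it gave 634 (0 h replicate 2) to 1799 (1 h replicate 2), with 719 and 658 without 0 h replicates 1 and 3 and 807 without 4 h replicate 2. For 4 h minus 1 h it gave 145 (4 h replicate 1) to 590 (1 h replicate 2), with 163, 146 and 146 without 0 h replicates 1, 2 and 3, 199 without 1 h replicate 1, and 152 and 196 without 4 h replicates 2 and 3. At 0 h it gave 4 (0 h replicate 2) to 1150 (1 h replicate 2), with 100 and 50 without 0 h replicates 1 and 3. Lists ran from 18 to 19, 14 to 15, 7 (without 1 h replicate 1) to 16 and 10 to 12, and shared calls from 203 (0 h replicate 2) to 577, with 252 and 221 without 0 h replicates 1 and 3. Residuals of arrays with the same replicate number correlated above 0.1 in 4 of 9 pairs, from -0.21 to 0.38. The others did so in 2 of 18, from -0.49 to 0.41. This does not settle whether the numbers pair the arrays, and they were not read as pairs. A replicate block gave 650, 1171, 213 and 625. A block for scan date or print batch was not run, since scan day follows time. Depth limits falls at 1 h most, where 2218 of 6380 probes had no treated signal above background.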

Other observations

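The gene groups and single genes in this part, and the tests on them, were chosen after the results were seen. Genes of reserve carbohydrates and glycerol were lower in the treated cultures. All 11 measured genes of trehalose, glycogen and glycerol synthesis fell at 4 h, with a median of -0.98 (camera adjusted p = 4.71e-12 over the 6 sets of this part, and adjusted p = 0.0191 with an estimated correlation), and 9 fell at 1 h, with a median of -0.81. TSL1 (-1.48 ± 0.11 at 4 h), of the trehalose synthase complex, PGM2 (-1.48 ± 0.10), the phosphoglucomutase, and GPP2 (-1.29 ± 0.08), a glycerol phosphatase, are examples. The larger part of this set, TPS1, TPS2, TSL1, PGM2, GSY1, GSY2 and GPD1, also belongs to the general stress list. The test of the set therefore largely repeats that of the list. Of 10 genes of daughter cell separation 9 fell at 4 h (median -0.71, camera adjusted p = 4.98e-09, and adjusted p = 0.019 with an estimated correlation) and 7 at 1 h (median -0.62). CTS1 (-1.24 ± 0.17 at 4 h), the chitinase that parts mother and daughter, SCW11 (-1.14 ± 0.15), DSE1 (-1.09 ± 0.06) and DSE2 (-1.10 ± 0.06) were among them.

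All 12 RNA polymerase II subunit genes lay above 0 at 4 h, of which 4 rose (median 0.45, camera adjusted p = 6.7e-05, and adjusted p = 0.019 with an estimated correlation), and 3 rose at 1 h (median 0.37). Beside RPO21, RPB8 rose by 0.67 ± 0.14, RPC10 by 0.72 ± 0.18 and RPO26 by 0.54 ± 0.14 at 4 h, and polymerases I and III share these 3 subunits. Of 19 genes of the mitochondrial genome 3 rose at 4 h, OLI1 (1.50 ± 0.29), VAR1 (2.62 ± 0.32) and COX3. The ratio of VAR1 went from -1.25 (SD 0.08, 2 arrays) at 0 h to 1.38 at 4 h. The treated signal of 17 of the 19 lay at background at 1 or more of the times, so the set as a whole is not read. COX3 was at background in the untreated channel at all 3 times, so no fold is given for it.

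SER3 encodes an enzyme of serine synthesis and CHA1 an enzyme of serine breakdown, and at 4 h they stood at 2.70 and -2.65. A candidate explanation is that the treated cells took up less serine or other amino acids. Genes of 8 amino acid permeases had a median of -0.42 at 4 h (SD over members 0.31). Without GNP1, which had values on only 2 arrays at 0 h and 2 at 1 h, they passed the fry test of limma as a set. GNP1 itself did not pass in the limma model at 4 h (-0.40 ± 0.19, adjusted p = 0.183). A fall of permease genes is not a measure of uptake. BAP2 (-1.00 ± 0.18), a branched-chain permease gene, and TAT1 (-0.44 ± 0.07), for tyrosine and other amino acids, were among those that fell. With AGP1 added, the 9 genes had a median of -0.44, and 6 of them fell (camera, again without GNP1, adjusted p = 0.000242, but adjusted p = 0.0846 with an estimated correlation). Their median was already -0.59 at 1 h and 0.09 for 4 h minus 1 h, with 0 called, while SER3 (1.38) and CHA1 (-1.39) moved further between the times. A wider change of serine and glycine synthesis genes is argued against, since 1 of 6 (SER2, 0.49 ± 0.09) passed in the direction of SER3 while GLY1 (-1.11 ± 0.18) and SHM2 (-0.88 ± 0.12) fell.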
